A study of Drosophila melanogaster with 6 samples.

How the data were processed

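Transcript levels were measured on 6 Affymetrix Drosophila arrays, 3 with RNA of oviducts from unmated females and 3 with RNA of oviducts from mated females. Per the labels, all females were 3 days old, mated females were dissected 3 h after mating, tracts of 400 to 500 females were pooled, RNA was extracted with TRIzol and the transcripts carried a biotin label. The labels call the arrays of a group biological repeats, and each array was counted as 1 replicate (n = 3 per group). They do not state whether the females were pooled per array or per group; with 1 pool per group, the spread between arrays would leave out the variation between pools.

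The deposited values are intensities on a linear scale, with 1 value per probe set and array. The submitters' processing notes name RMA without a version, and no other step is given in the sources used here. The values do not have the form RMA usually gives. They are not on a log2 scale, and their quartiles differ between arrays, whereas the mean over the middle 96% of the values is 250 on every array. The intensities were therefore treated as values that had been scaled by 1 factor per array, and which summary the authors used remains unknown. Detection calls were not used here, so a dim probe set could not be separated from background.

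The file held 14010 probe sets. The 44 Affymetrix control probe sets were left out of the tests, which left 13966. Names came from the platform annotation, in which 12443 of these probe sets had 1 gene, 327 had several genes and 1196 were not listed. Symbols of 12394 probe sets were updated through Entrez identifiers against RefSeq genes of the assembly Release 6 plus ISO1 MT, used only for names. No gene was named from a probe set with several genes. For each of the 10844 genes, the probe set with the highest mean log2 value over the 6 arrays was used.

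Mated and unmated arrays were compared on the log2 of the deposited intensity, with no offset, filter or further normalization, by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3. Benjamini-Hochberg adjustment covered all 13966 probe sets, and the threshold was an adjusted p of 0.05. For 32 gene lists, each given with its result in the text that follows, limma's camera with a preset correlation of 0.01 tested the list against all other genes, adjusted over the 32 lists. Camera with an estimated correlation and limma's fry were run beside it. Control probe sets were compared by exact permutation tests over the 6 arrays, two-sided, whose smallest possible p is 0.1.

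The gene lists, the tests, the thresholds and all alternatives other than 3 were fixed before the data were examined. The rule for named genes was fixed with them. It took the genes with the largest fold among those that passed the adjusted threshold with groups that did not overlap, up to 4 members of each list with the smallest p, and, where fewer than 10 genes passed in a direction, those with the smallest p among genes whose groups did not overlap, up to 10 per direction. No gene passed, so the last 2 parts supplied the names. Genes known only by a CG number may be summarised by count.

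The alternatives were quantile normalization, median centring, cyclic loess, only probe sets above the median of mean levels, a variance model with trend and robust settings, array weights, the replicate number as a block, each array left out in turn, a 1.5-fold minimum, an adjusted p of 0.01, camera with an estimated correlation, and the mean of a gene's probe sets. An offset of 32 before log2, the omission of unmated arrays 1 and 2 and the omission of Rrp1 from ribosome biogenesis were added after the values had been seen.

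The tests were also run on simulated data with the array number and the spread of these arrays. Each probe set's spread was drawn from a common distribution, whatever its level, and the simulated arrays were independent. The recovered shares therefore do not give the sensitivity for bright or for dim probe sets. Among 13966 simulated probe sets with 200 changed, over 20 runs, limma recovered 0% at 2-fold, 0% at 4-fold and 60.6% at 8-fold. At 8-fold, 2424 changed and 130 unchanged probe sets were called in all. For a 25-gene list among 10844 independent genes, over 50 runs, camera called 4% of lists with no shift and 100% of lists with a shift of 0.5 on the log2 scale. The genes of the real lists were not independent, with an estimated correlation of up to 0.556 in a list. The 4% therefore does not carry over to them. The precision of every value is limited by the number of arrays. Over the arrays, the ratio of 3' end to 5' end of the control probe sets ran from 17.1 to 29.3 for GAPDH. For actin it ran from 29.7 to 42.0. How such a 3' bias affects the intensities was not tested.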

Results

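The data describe the oviduct of the fruit fly Drosophila melanogaster, the duct through which eggs pass from the ovary, in unmated females and in females dissected 3 h after mating. Each group had 3 arrays. Intensities ranged from 0.2 to 30276.7. The median intensity of the probe sets was 86.2 and 86.0 on unmated arrays 1 and 2, 62.4 on unmated array 3, and 66.5, 66.1 and 60.6 on mated arrays 1, 2 and 3. Unmated arrays 1 and 2 also stood apart in the 18S rRNA and spike-in control probe sets. The mean intensity of the 18S rRNA controls was 846 and 652 there, against 187 on unmated array 3 and 140, 371 and 310 on the mated arrays. The mean intensity of the hybridisation spike-in controls was 429 and 415 there, against 777 on unmated array 3 and 644, 861 and 707 on the mated arrays. Over the probe sets brighter than the median, the highest correlation between any 2 arrays, taken across probe sets, was 0.951, between unmated array 3 and mated array 1.

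The comparison asked which transcripts of the oviduct differ after mating; the series title names an immune response and a developmental switch. Genes of DNA replication, markers of ovary, eggshell and germline, and markers of midgut and Malpighian tubule lay lower in mated oviducts than in unmated ones, relative to all genes. Genes of basement membrane and matrix, of the secretory pathway and of ribosome biogenesis lay higher. These 6 lists were the ones past the camera threshold, out of 32, but 0 of the 32 passed with an estimated correlation between genes and 0 passed without unmated arrays 1 and 2, in a fit of 1 array against 3. In that fit the relative median log2 difference was -0.19 for DNA replication, -0.04 for ovary and -0.19 for midgut, against -0.75, -0.78 and -0.77 with all arrays. It was 0.39 for basement membrane, 0.20 for the secretory pathway and 0.46 for ribosome biogenesis, against 0.31, 0.36 and 0.37. No single gene passed the limma test.

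At an adjusted p of 0.05, limma called 0 probe sets higher and 0 lower in mated oviducts, and the lowest adjusted p was 0.477. At an unadjusted p of 0.05, 145 probe sets were higher and 776 lower, 921 in all, where 698 are due by chance. With trend and robust settings these counts were 163 and 641, again with 0 past the adjusted threshold. The split depended on scaling, with 327 higher and 420 lower after quantile normalization, 325 and 447 after median centring, and 349 and 401 after cyclic loess. The median log2 difference of all genes was -0.16 with the deposited scaling and 0.11 after median centring, so lists are given relative to that median. Leaving out 1 array moved the relative median by over 1.5 times in 30 of the 32 lists and turned its sign in 9. The 3 mated values lay above all 3 unmated values in 326 probe sets and below them in 1199, together 10.9% of probe sets, where chance gives 10%. Without unmated replicate 3 the unadjusted counts were 292 higher and 1728 lower; the lower count was 433 without unmated replicate 1, 458 without unmated replicate 2 and 445 without mated replicate 3.

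Among genes whose groups did not overlap, LUBEL, the fly linear ubiquitin ligase, had an intensity of 32 ± 3.40 in unmated and 118 ± 5.25 in mated oviducts (SD, n = 3 each), a log2 difference of 1.89 ± 0.30 (SE). The neprilysin-like gene Nepl19 had 13.0 ± 1.91 and 53.2 ± 9.91. The gene defl, which encodes a subunit of the Integrator complex, had 91.5 ± 29.8 and 311 ± 65.5. Mmp2, a matrix metalloproteinase, had 25.1 ± 1.94 and 65.0 ± 11.3, and the cytochrome P450 gene Cyp4ae1 had 16.2 ± 2.61 and 45.6 ± 11.5. CG10657 had the largest of these differences, 2.38 ± 0.42 on the log2 scale, with 99.1 ± 32.4 and 518 ± 168. The remaining 4 of the 10 genes named as higher are known by CG numbers. None of the 10 passed, with adjusted p from 0.541 to 0.621 in limma.

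On the lower side, dpa, which encodes the Mcm4 subunit of the replicative helicase, had an intensity of 103.5 ± 15.2 in unmated and 15 ± 6.77 in mated oviducts (SD, n = 3 each), a log2 difference of -2.87 ± 0.40 (SE). Orc1, a subunit of the origin recognition complex, had 107 ± 37.9 and 22.1 ± 3.45. Prim2, the large subunit of DNA primase, had 82.5 ± 37.3 and 13.3 ± 1.33. The gene gprs had 115 ± 8.28 and 37.2 ± 4.04, and the gene BG642163 had 27.7 ± 1.5 and 8.87 ± 0.924. CG42521 had 106 ± 63.5 and 6.27 ± 3.36; its mated values of 7.9, 8.5 and 2.4 lie below the lowest lower quartile of any array, 14.2, so the size of its difference is not exact. The same limit holds for every other intensity under 14.2 given here. Another 4 genes with CG numbers completed the 10. None passed, with adjusted p from 0.541 to 0.585 in limma. All 20 genes named here kept the sign of their difference under every alternative in which they were tested, but sizes shrank with 32 added before log2, to 1.23 for LUBEL, 0.92 from 2.03 for Nepl19, 0.36 from 2.05 for CG13021, -1.53 for dpa and -1.76 for CG42521. The kept sign is little evidence, because these genes were chosen for groups that did not overlap. Only quantile normalization, median centring and cyclic loess could have turned it.

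**Figure D1:**
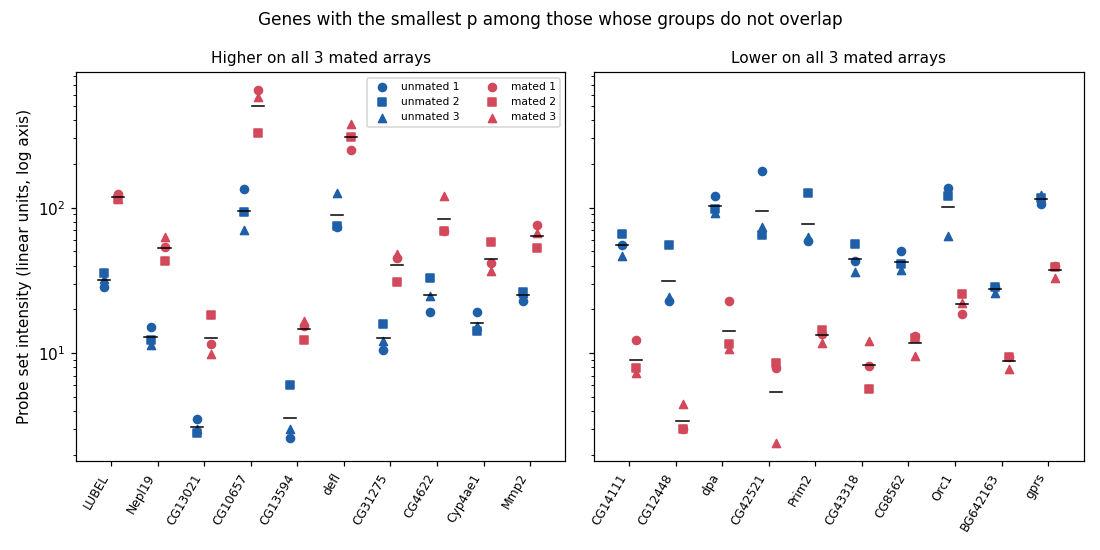
Intensity on a log axis of the 10 genes named as higher (left) and the 10 named as lower (right) in mated oviducts; each symbol is 1 array, blue for unmated and red for mated, and bars are geometric means of 3 arrays. For LUBEL the mated arrays lie between 115.1 and 124.2 and the unmated arrays between 28.5 and 35.3; for dpa the mated arrays lie between 10.6 and 22.8 and the unmated arrays between 91.3 and 120.6.

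Of 22 measured genes of DNA replication and cell cycle, 21 lay below the all-gene median, and the list's median log2 difference was -0.75 relative to all genes. Among them 7 had an unadjusted p under 0.05, 0 passed over all probe sets, and 3 were lower adjusted over the list alone. These 3 were dpa, Orc1 and Orc2, and Orc2 had intensities of 25.8 ± 13.4 and 5.37 ± 0.379 (SD, n = 3 each). RnrL, the large subunit of ribonucleotide reductase, had 136 ± 42.6 and 51.8 ± 23.7. Camera gave the list an adjusted p of 5.78e-06, and an adjusted p of 0.673 with an estimated correlation, which was 0.415 between its genes. The list's level, relative to all genes and to each gene's mean over the arrays, was 0.72 and 0.81 on unmated arrays 1 and 2, -0.21 on unmated array 3 and -0.40, -0.31 and -0.27 on the mated arrays. Without unmated arrays 1 and 2 the relative median was -0.19, with a camera adjusted p of 0.504; over all alternatives the adjusted p ran from 5.11e-08 to 0.673.

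Markers of ovary and gut also lay lower in mated oviducts. Of 30 measured genes of ovary, eggshell and germline, 24 lay below the all-gene median, with a relative median log2 difference of -0.78, 9 had an unadjusted p under 0.05 and 0 passed, also adjusted over the list alone. The chorion genes Cp38, Cp18 and Cp16, which encode eggshell proteins, had intensities of 658 ± 581, 1010 ± 366 and 371 ± 317 in unmated and 73.2 ± 39.3, 444 ± 106 and 23.4 ± 2.81 in mated oviducts (SD, n = 3 each). Cp16 stood at 645 and 445 on unmated arrays 1 and 2, at 23.3 on unmated array 3 and at 25.3, 24.8 and 20.2 on the mated arrays. The fourth named member, yellow-g2, had 201 ± 66.6 and 53.8 ± 31.9. Camera gave an adjusted p of 0.000178, and an adjusted p of 0.675 with an estimated correlation. In all, 4 members also stand in other lists.

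Of 27 measured genes of midgut and Malpighian tubule, 24 lay below the all-gene median, with a relative median log2 difference of -0.77, 7 had an unadjusted p under 0.05 and 0 passed, also adjusted over the list alone. The trypsin gene betaTry stood at 537 and 963 on unmated arrays 1 and 2, at 36.6 on unmated array 3 and at 37.9, 32.9 and 23.1 on the mated arrays. The maltase gene Mal-A1 had intensities of 273 ± 168 and 57.1 ± 35.7 in unmated and mated oviducts, and the Jonah serine protease genes Jon65Aiii and Jon65Aiv had 517 ± 226 and 352 ± 234 against 207 ± 55.3 and 76.7 ± 42.8 (SD, n = 3 each). Camera gave an adjusted p of 1.13e-05, and an adjusted p of 0.673 with an estimated correlation. On unmated arrays 1 and 2 the relative level was 0.72 and 0.58 for the ovary list and 0.84 and 0.60 for the midgut list, against -0.21 and -0.25 on unmated array 3. Without unmated arrays 1 and 2 the relative median was -0.04 for the ovary list and -0.19 for the midgut list, with camera adjusted p of 0.788 and 0.691, the highest of their alternatives; the lowest were 6.82e-09 and 4.34e-08. The ovary value was -0.43 without mated replicate 2, and the midgut value was -1.30 without unmated replicate 3.

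Of 22 measured genes of basement membrane, matrix and integrins, 19 lay above the all-gene median, with a relative median log2 difference of 0.31. Besides Mmp2, the basement membrane gene Ndg, which encodes nidogen, had intensities of 16.7 ± 7.41 in unmated and 42.3 ± 7.15 in mated oviducts (SD, n = 3 each), pio had 5764 ± 669 and 7537 ± 854, and the integrin subunit gene Itgbn had 69.7 ± 42.4 and 102 ± 36.8. Mmp2 and Ndg had an unadjusted p under 0.05, and 0 members passed, also adjusted over the list alone. Camera gave an adjusted p of 0.00402, and an adjusted p of 0.673 with an estimated correlation. Against unmated array 3 alone the relative median was 0.39, and against unmated arrays 1 and 2 it was 0.32. The call was lost after quantile normalization (relative median 0.13), after cyclic loess (0.15), among probe sets above the median level (0.15), without mated replicate 2 (0.19), without mated replicate 3 (0.18) and, at a larger value, without unmated arrays 1 and 2 (0.39), while the value without mated replicate 1 was 0.51.

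Of 27 measured genes of the secretory pathway and ER folding, 25 lay above the all-gene median, with a relative median log2 difference of 0.36. The list's relative level was -0.48, -0.08 and 0.04 on unmated arrays 1, 2 and 3. It was 0.26, -0.11 and 0.57 on mated arrays 1, 2 and 3, so the groups overlapped. Sec24CD, a coat protein of ER vesicles, had intensities of 104 ± 32.9 and 160 ± 32.5, KdelR, the receptor that returns ER proteins, had 1076 ± 330 and 1771 ± 724, and Srp68, a signal recognition particle subunit, had 487 ± 60.5 and 693 ± 124 in unmated and mated oviducts (SD, n = 3 each). Sec61alpha, the channel of the translocon, had a log2 difference of 0.60 ± 0.39 (SE). No member had an unadjusted p under 0.05 or passed adjusted over the list alone. Camera gave an adjusted p of 0.000178, and an adjusted p of 0.673 with an estimated correlation. The call was lost after quantile normalization (relative median 0.10), after cyclic loess (0.13), without mated replicate 3 (0.25) and without unmated arrays 1 and 2 (0.20), and the value was 0.17 without unmated replicate 1, 0.58 without unmated replicate 3 and 0.63 without mated replicate 2.

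Of 29 measured genes of ribosome biogenesis, 24 lay above the all-gene median, with a relative median log2 difference of 0.37. The 4 members with the smallest p did not all share this direction. Rrp1 and mbm had log2 differences of -0.85 ± 0.34 and -0.78 ± 0.57, and CG8939 and Ns2 had 0.75 ± 0.62 and 0.45 ± 0.40 (SE). In the fly Rrp1 encodes a DNA repair endonuclease; with it left out, a choice made after seeing the data, 28 genes had a relative median of 0.38 and 0 had an unadjusted p under 0.05. Camera gave an adjusted p of 0.0498, and an adjusted p of 0.769 with an estimated correlation, which was 0.556 between its genes; 0 members passed adjusted over the list alone. The call was lost in 12 of 18 alternatives, over which the adjusted p ran from 1.42e-07 to 0.855. The value stayed at 0.37 after median centring and with the replicate block, and was 0.46 without unmated arrays 1 and 2. Other losses included quantile normalization (0.32), cyclic loess (0.30) and the use of only probe sets above the median level (0.29). They also included the omission of mated replicate 3 (0.16), of unmated replicate 1 (0.21), of mated replicate 1 (0.24) and of unmated replicate 3 (0.43). Without mated replicate 2, where the call held, the relative median was 0.89.

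No immune list passed with the main settings. The list of antimicrobial and other induced immune peptides held 32 genes, of which only 12 were measured. Of these, 5 lay above and 7 below the all-gene median, with a relative median log2 difference of -0.64 and a camera adjusted p of 0.552. The value was -0.35 without unmated replicate 1, -0.36 without unmated replicate 2, -0.33 without mated replicate 1, -1.13 without unmated replicate 3 and 0.29 without unmated arrays 1 and 2. The diptericin gene DptB stood at 231, 253 and 222 on the unmated arrays and at 512, 1466 and 252 on mated arrays 1, 2 and 3. The attacin gene AttD had intensities of 89.2 ± 54.2 and 16.3 ± 8.34, and BomS2 and IM33 had 134 ± 70.5 and 1152 ± 662 in unmated against 44.5 ± 15.4 and 423 ± 131 in mated oviducts (SD, n = 3 each). The list's relative level was 0.69 and 0.60 on unmated arrays 1 and 2, -0.61 on unmated array 3 and -0.22, -0.33 and -0.64 on the mated arrays. Immune recognition genes and opsonins had a relative median of 0.29 over the 12 measured of 23 listed genes (camera adjusted p 0.162). The relative median was 0.14 without mated replicate 3, 0.18 without unmated replicate 1, 0.45 without unmated replicate 3 and 0.00840 without unmated arrays 1 and 2. PGRP-SB1, a peptidoglycan recognition gene, stood at 39.3, 42.4 and 163 on the unmated arrays and at 311, 55.4 and 209 on the mated arrays, and Tep3 had 205 ± 102 and 419 ± 206. Genes of Toll, Imd, JAK-STAT and Turandot signalling had a relative median of 0.17 over 27 genes (camera adjusted p 0.146) and passed without mated replicate 1 (0.31, adjusted p 0.0204), and TotB had intensities of 23.6 ± 16.2 and 6 ± 2.04, all 3 mated values below 14.2. Serpins had 0.23 over 26 genes (0.146) and haemocyte markers -0.17 over 13 genes (0.408; 0.22 without mated replicate 1), among them the prophenoloxidase gene PPO1 with 100.5 ± 44.8 and 42.6 ± 32.6. No member of these 5 lists passed, also adjusted over the list alone.

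Lists of tissue structure and signalling did not pass with the main settings either. The relative median log2 difference was 0.21 for 26 septate junction genes (camera adjusted p 0.158), 0.06 for 15 adherens junction and polarity genes (0.347), 0.22 for 27 muscle and sarcomere genes (0.146), 0.17 for 24 genes of the actin and microtubule cytoskeleton (0.0879) and -0.05 for 35 cuticle and chitin genes (0.758). Cuticle and chitin passed among probe sets above the median level (-0.41, adjusted p 0.0199), muscle without unmated replicate 3 (0.39, 0.0197) and the cytoskeleton without mated replicate 1 (0.31, 0.0204). In the cytoskeleton list, the filamin gene cher had intensities of 4519 ± 774 in unmated and 6767 ± 762 in mated oviducts (SD, n = 3 each), with groups that did not overlap. In the septate junction list, mesh had 242 ± 40.5 and 146.5 ± 33.4, and in the muscle list, sls had 906 ± 304 and 1482 ± 518. The muscle genes TpnC4 and fln had smaller p than sls and were lower, with 5.6 ± 4.50 and 11.7 ± 7.02 against 1.9 ± 1.08 and 4.5 ± 2.05. TpnC41C was lower as well, with 9.67 ± 5.45 and 4.9 ± 2.05. Developmental signalling genes had a relative median of -0.02 over 20 genes (0.994), although kek1, a gene of the EGFR pathway, had 24.8 ± 11.7 and 86.3 ± 43.6. Genes of the ecdysone and juvenile hormone response had 0.20 over 21 genes (0.158), nervous system and synapse genes -0.05 over 21 genes (0.852), immediate early and JNK genes 0.25 over 9 genes (0.146) and circadian clock genes 0.28 over 8 genes (0.411). The JNK pathway genes Jra and bsk had 554 ± 131 and 517 ± 53.7 in unmated against 881 ± 132 and 731 ± 21.2 in mated oviducts, each with groups that did not overlap. The value turned to -0.0120 without unmated replicate 3 for adherens junctions, to 0.09 without unmated replicate 1 and 0.21 without mated replicate 1 for developmental signalling, and to 0.10, 0.18 and 0.0252 without unmated replicate 1, unmated replicate 3 and mated replicate 3 for the nervous system. The sign of the relative median turned after quantile normalization and cyclic loess for the muscle, cuticle and nervous system lists, and after cyclic loess for the cytoskeleton list.

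Among metabolic and protein lists, the relative median log2 difference was 0.20 for 61 genes of oxidative phosphorylation (camera adjusted p 0.0808), 0.17 for 64 mitochondrial ribosomal proteins (0.0808), 0.02 for 37 cytosolic ribosomal proteins (0.887), 0.18 for 11 glycolysis genes (0.513), 0.11 for 26 proteasome genes (0.607), 0.34 for 9 heat shock and stress genes (0.653) and -0.09 for 45 detoxification genes (0.607). Oxidative phosphorylation passed after median centring, with array weights, with 32 added before log2, without unmated replicate 3 (0.42) and without mated replicate 1, and its adjusted p ran from 0.00171 to 0.805 over the alternatives. Mitochondrial ribosomal proteins passed after median centring, with array weights, without unmated replicate 3 and without mated replicate 2 (0.31), with a range from 0.000255 to 0.992. Cytosolic ribosomal proteins passed as lower after cyclic loess (-0.23, adjusted p 0.0262). The sign turned for the proteasome without unmated replicate 1 (-0.0133), for cytosolic ribosomal proteins without unmated replicate 2 (-0.0498) and for detoxification without unmated replicate 3 (0.0334). The mitochondrial ribosomal protein gene mRpL24 had intensities of 830 ± 111 and 1400 ± 206, the small heat shock gene Hsp26 had 550 ± 257 and 150.0 ± 34.6, and the glutathione S-transferase gene GstE9 had 101.5 ± 24 and 28.9 ± 20.7 in unmated and mated oviducts (SD, n = 3 each). Oxidative phosphorylation, cytosolic ribosomal proteins, glycolysis and the proteasome had the opposite sign after quantile normalization and cyclic loess. Relative medians, relative means and camera directions differed in sign for cytosolic ribosomal proteins, cuticle and chitin, developmental signalling, the nervous system and spermathecal secretory cells; camera placed the first 2 lower and the others higher. For the heat shock list camera followed the median although Hsp26 and Hsp27, with 254 ± 145 and 93.0 ± 11.4, had the smallest p.

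Markers of male tissues and of other female tissues gave no further call with the main settings. The relative median log2 difference was -0.29 for 24 genes of male accessory gland and ejaculatory duct (camera adjusted p 0.163), -0.10 for 26 testis and sperm genes (0.404), 0.15 for 8 genes of spermathecal secretory cells (0.653) and -0.33 for 20 fat body genes (0.143). The male accessory gland value was -0.12 without mated replicate 3, -0.54 without mated replicate 2 and -0.66 without unmated replicate 3, and lay at -0.0211 after quantile normalization, at -0.0250 after cyclic loess and at -0.00159 without unmated arrays 1 and 2. The fat body list passed as lower after cyclic loess, among probe sets above the median level, with trend and robust settings and with 32 added before log2, and its adjusted p ran from 0.00471 to 0.717 over the alternatives. Acp26Aa, a seminal fluid protein gene, had intensities of 5.87 ± 0.153 in unmated and 2.20 ± 0.721 in mated oviducts (SD, n = 3 each). In the testis list, djl and twe had an adjusted p of 0.0404 in limma over the list alone, but djl, with 2.80 ± 0.265 and 1.07 ± 0.208, and Acp26Aa lie below 14.2 on all 6 arrays and are not shown to be above background. The gene twe, a Cdc25 phosphatase of meiosis, had 56.3 ± 23.3 and 14.0 ± 4.42. The yolk protein genes Yp1 and Yp3, which also stand in the ovary list, had 8933 ± 3254 and 6557 ± 2193 against 4671 ± 1238 and 3279 ± 753. Send2, of the spermathecal list, had 31.8 ± 12.5 and 40.6 ± 14.3. In that list CG32833 and CG32834 had smaller p and were lower, with 9.13 ± 11.7 and 58.2 ± 62.4 against 1.27 ± 0.666 and 20.7 ± 11.8. Spn88Ea was higher, with 7371 ± 954 and 9386 ± 1413. The sign of the testis median turned after quantile normalization, after cyclic loess, without unmated replicate 1 (0.12) and without mated replicate 3 (0.0121), and that of the spermathecal list without unmated replicate 3 (-0.09) and without mated replicate 2 (-0.13). Over all 32 lists, 0 calls held with an estimated correlation, and limma's fry gave the DNA replication list its lowest p, 0.0736 for 1 direction and 0.0345 for either direction.

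**Figure D2:**
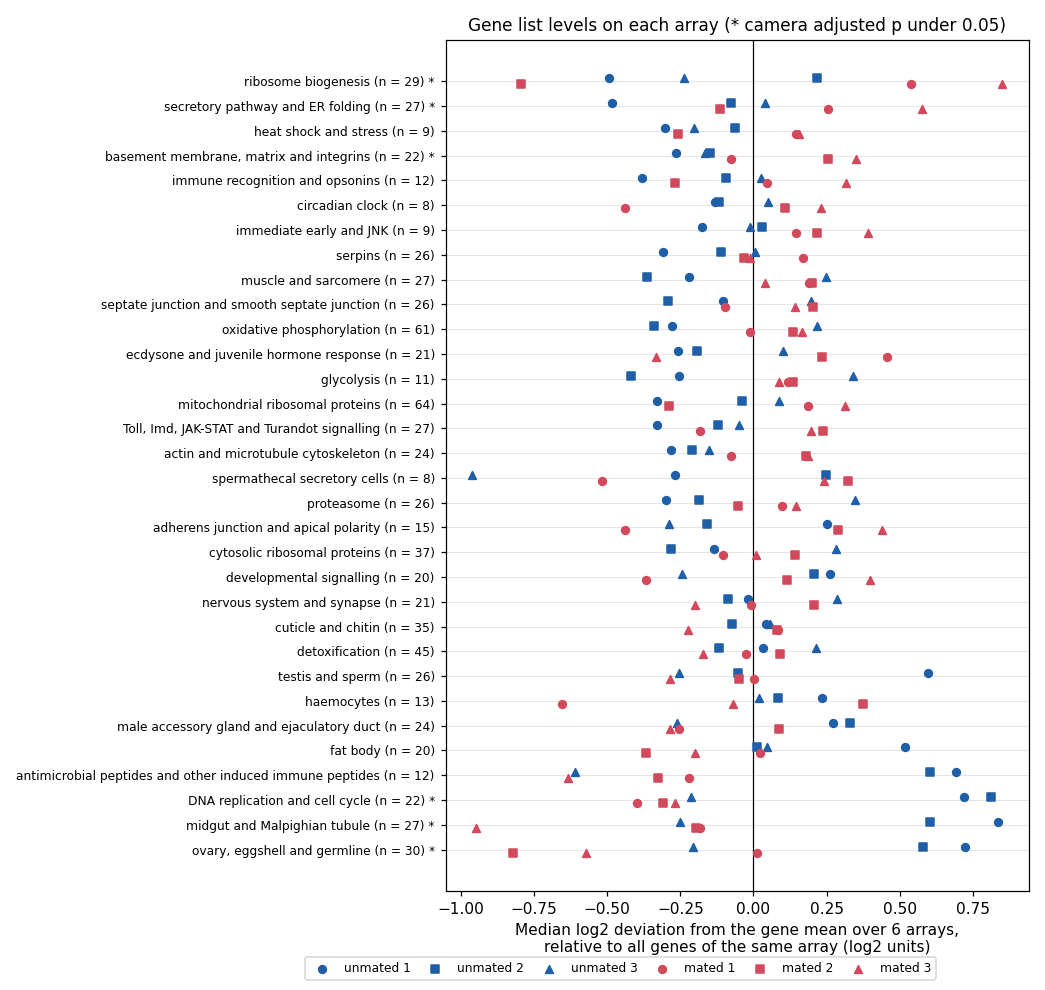
Level of each of the 32 gene lists on each array, as the median over its genes of the log2 deviation from the gene's mean over 6 arrays, relative to all genes of that array; blue symbols are unmated and red symbols mated arrays, n is the number of measured genes and an asterisk marks a camera adjusted p under 0.05. In the DNA replication list unmated arrays 1 and 2 lie at 0.72 and 0.81 and the other 4 arrays between -0.40 and -0.21; in the ribosome biogenesis list the mated arrays lie at 0.54, -0.80 and 0.85.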

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

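The tests of the midgut and ovary lists, the test of mating for the DNA replication list and the omission of unmated arrays 1 and 2 were chosen after the results had been seen. The test of the further replication genes was written before their values were seen.

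The hybridisation spike-in controls, which take no part in the comparison of genes, stood 0.50 higher on the log2 scale in mated than in unmated arrays. Their log2 means were 9.52 ± 0.21 and 9.01 ± 0.51 (SD, n = 3 each), and the exact permutation p was 0.3, where 0.1 is the smallest possible.

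Midgut and ovary markers lay lower in mated oviducts, and unmated arrays 1 and 2 held most of the excess. An array-wide shift of dim probe sets on those 2 arrays is not excluded, but level alone gave a smaller shift than the midgut list had. The midgut median between them and unmated array 3 was 1.40 on the log2 scale (1.09 relative to all genes). It lay at the 100th percentile of 10000 random lists of matched level. Those lists had a median of 0.39, so such a shift could account for part. The percentile cannot decide further, because the midgut list was picked for its height on these arrays. Random lists also lack the correlation estimated between its genes, 0.507. Tissue of gut and ovary carried over at dissection could be the cause, if each array had its own pool, which the labels do not state, but this is not decided: 85.2% of the midgut members were higher on both arrays than on unmated array 3, against 52.4% of all genes, and this share restates what prompted the explanation. Lists of other origin also lay higher on those arrays than on unmated array 3. The relative median was 1.53 for 8 genes of spermathecal secretory cells (75% of them) and 0.89 for antimicrobial peptides (75%). It was 0.71 for the male accessory gland list (58.3%), 0.56 for testis (57.7%) and 0.44 for developmental signalling (80%). On the same measure it was 1.09 for midgut and 0.85 for ovary (90%). Lists that lay lower there included glycolysis (-0.81) and muscle (-0.68). Mating stays open: unmated array 3 lay above all 3 mated arrays in 14.8% of the midgut members, where 25% are due by chance and 22.3% of all genes did so, but a single array cannot decide it.

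The DNA replication list had the same arrays at its top. Tissue with dividing cells carried over on those arrays could be the cause but is not decided. In a further list of 47 replication and mitosis genes, unmated array 3 lay above all 3 mated arrays in 12.8% (6 genes), against 22.3% of all genes. The exact binomial 95% interval, 4.83% to 25.7%, holds the 25% that chance gives. That interval takes the genes as independent, whereas those of the DNA replication list had an estimated correlation of 0.415. A similar correlation in the further list would make it wider. No change, or any other cause confined to those 2 arrays, would give the same. In the fixed list the share was 31.8%, and it included dpa, Orc1, Orc2 and RnrL, the 4 members with the smallest p. For dpa, unmated array 3 stood at 91.3 and the mated arrays at 22.8 or less. A choice by smallest p favours such genes, and unmated array 3 lay below all 3 mated arrays in 18.2% of the list, against 22.8% of all genes. These shares come from a single array that cannot decide on mating. Mating therefore stays open as well.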

How the results depend on the processing

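The offset of 32, the omission of unmated arrays 1 and 2 and the omission of Rrp1 from ribosome biogenesis (6 lists passed) were chosen after seeing the data. Limma called 0 probe sets higher and 0 lower in all 17 alternatives for each direction. The number of gene lists past the camera threshold, 6 with the deposited scaling, was 3 after quantile normalization, 0 with an estimated correlation, 0 without unmated arrays 1 and 2, and between 3 and 8 when each array was left out in turn, with 3 without mated replicate 3; apart from the estimated correlation, whose construction widens the error, the cause was not tested. The fit without unmated arrays 1 and 2 sets 1 array against 3 and assumes that the lone array varies like the mated ones. The labels state no pairing. The residuals of arrays with the same number correlated at -0.18, 0.03 and -0.09, and no array correlated best with its own number: the highest were unmated 3 with mated 1 (0.25), unmated 1 with mated 2 (0.17) and unmated 2 with mated 3 (0.10). Among probe sets above the median level these were 0.45, 0.42 and 0.39, against -0.40, -0.11 and -0.30 for the same numbers. With the replicate number as a block 5 lists passed, without ribosome biogenesis. Blocked on those crossed pairs, chosen after seeing the data as the best of 6 pairings, limma called 0 probe sets, with 1167 at an unadjusted p of 0.05, and 6 lists passed. For the 6 lists, 73 results under alternatives kept direction and call and 30 lost the call; none turned. For the named genes tested there, 594 results kept their sign and 1 turned, Cp16, at 0.000948 on the log2 scale without unmated arrays 1 and 2 (the cause was not tested). No named gene had a call to lose. Those chosen for groups that did not overlap could turn only after a renormalization. The antimicrobial peptides and 8 lists that passed only under some alternative were followed too. Camera turned their direction, with no call, for the antimicrobial peptides at 0.29, oxidative phosphorylation at -0.14, muscle at -0.14 and mitochondrial ribosomal proteins at -0.0153 without unmated arrays 1 and 2; the causes of these turns were not tested. It also turned for oxidative phosphorylation after quantile normalization (-0.016) and cyclic loess (-0.0296), muscle after cyclic loess (-0.0362), and cuticle after quantile normalization (0.0109), cyclic loess (0.0431) and without mated replicate 3 (-0.0228). Cytosolic ribosomal proteins turned after median centring (0.0237), with array weights (0.13), with the replicate block (0.0237), without unmated replicate 3 (0.18) and without mated replicate 1 (0.14); without unmated replicate 2 the value was -0.0498, and the cuticle value without unmated replicate 3 was -0.17. Signal over background could not be judged without detection calls.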

Other observations

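The further list of replication and mitosis genes was written after the DNA replication list had been seen. By the raw log2 difference, 37 of 47 genes were lower and 10 higher in mated oviducts. That count makes no allowance for the all-gene median of -0.16, unlike the counts of the other lists. In limma, 7 had an unadjusted p under 0.05, all of them lower, where 776 of the 921 probe sets at that threshold were lower. Cenp-C, a protein of the centromere, stood at 79.8, 93.5 and 32.3 on unmated arrays 1, 2 and 3 and at 20.6, 14.7 and 10.2 on the mated arrays. Incenp, a subunit of the chromosomal passenger complex, stood at 91.9, 70.2 and 41.8 against 21.9, 14.1 and 43.9, and ana2, a centriole gene, at 360.4, 159.6 and 175.4 against 121.6, 87.5 and 57.3. For feo the values were 169, 104 and 14.7 against 12.6, 10.7 and 11.9, and for SMC2 60.1, 94.9 and 10.6 against 8.9, 6.3 and 14.7. These 5 genes, all of them lower, were named after their values had been seen. Of the 10 higher genes, also picked by value, Prim1 stood at 18.9, 28.5 and 64.8 against 60.6, 78.6 and 47.6. PolE2 stood at 21.7, 23.3 and 23.1 against 26.2, 26.3 and 31.3. The median log2 difference of the list relative to all genes was -0.24, with a camera p of 0.0032 in limma and a p of 0.378 with an estimated correlation. The relative median was 0.03 between the mated arrays and unmated array 3 and 0.56 between unmated arrays 1 and 2 and unmated array 3.

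Ribosome biogenesis genes varied between arrays of both groups, with relative levels of -0.49, 0.22 and -0.24 on unmated arrays 1, 2 and 3 and of 0.54, -0.80 and 0.85 on mated arrays 1, 2 and 3.

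The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 6 lists past the camera threshold, the highest of the others 11, and 5 of the 10 splits gave at least as many as the real one. The split with 11 lists set unmated arrays 1 and 2 with mated array 1 against the rest. All 10 splits gave 0 probe sets past the adjusted threshold over all probe sets. Among probe sets above the median level, the split with unmated arrays 1 and 3 and mated array 2 against the rest gave 2. The real split gave 0 there. At an unadjusted p of 0.05 over all probe sets, the real split gave 921 probe sets in limma. The highest of the others gave 2062, with unmated arrays 1 and 2 and mated array 2 against the rest. Those arrays also had the highest ratios of 3' end to middle for actin, 1.55, 1.43 and 1.58, against 1.01 or less elsewhere. For GAPDH that ratio did not set them apart, with 2.19, 2.32 and 2.48 there. It was 2.12 on unmated array 3 and 3.53 and 2.35 on mated arrays 1 and 3. The ratios of 3' end to 5' end did not set them apart for either control. A link to the actin ratio was not tested.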
